A study of Mus musculus with 12 samples.

How the data were processed

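RNA sequencing was analysed from 2 deposited gene tables of the same 12 libraries, one of counts and one of RPKM. Per the labels' protocols, LSK cells were sorted from bone marrow and irradiated or sham-incubated, RNA was isolated with an AllPrep DNA/RNA/miRNA kit, and stranded libraries were made with KAPA RNA HyperPrep after ribosomal RNA removal. Per the submitters' processing notes the tools were bcl2fastq 2.18.0.12, TopHat2 and HTSeq 0.6.1p1 with build mm10. The role and settings of each tool, the strand setting, the annotation release and any read filter are not given in the sources used here. Because the strand setting is not stated, genes that overlap on opposite strands are uncertain, as are close paralogs. Coordinates are those of the deposited tables, 1 span per gene.

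The deposited count table, with whole numbers per gene and 1 column per library, was used for every main result. The deposited RPKM values are counts scaled to exon length and to a library size that the tables show to be 0.950 to 1.04 times the total gene count of the library, and 1.01 to 1.02 times its TMM effective size. They were used only in alternatives. Both tables hold 25078 genes, of which 4353 had 0 counts in all 12 libraries, and no column belonged to another sample. Mitochondrially encoded mRNAs were not analysed here. Total gene counts were 68.5, 89.5 and 76.2 M in WT NIR animals 1, 2 and 3, 83.3, 92.4 and 110.8 M in WT IR, 79.9, 77 and 77.9 M in CM NIR, and 88.5, 83 and 84.5 M in CM IR. At this depth counting error is small beside the spread between animals for most named genes; genes under 1 CPM are less precise.

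Groups came from the sample titles, and animals from the labels. The titles call the unmutated group control and its genotype label is WT in all 6 libraries, while the library names mark animals 1 and 3 as C and animal 2 as WT; what C stands for is not stated. Deviations from the group means correlated between the NIR and IR libraries of an animal at 0.67, 0.50 and 0.41 in WT and at 0.79, 0.84 and 0.13 in CM, and the labels give each NIR and IR pair 1 animal number, so they were taken as paired by animal and the replicate block is the animal. The last pair, CM animal 3, is an exception: its NIR library correlated at 0.69 with the IR library of CM animal 1. Library numbers in the labels fall into 2 series: WT animal 1 and CM animals 1 and 2 are in A, and WT animals 2 and 3 and CM animal 3 are in B. The series hold 1 or 2 animals of a genotype, so they were used as an additive term and not fitted apart. Every pair of libraries differed by more than sampling noise (chi-square over its degrees of freedom at least 14.8).

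Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 14599. All 12 libraries were fitted with 1 mean per group and no term for the animal, TMM normalization and edgeR's quasi-likelihood test; the common biological coefficient of variation was 0.290 and the prior degrees of freedom 2.41. The 5 contrasts were IR against NIR in WT and in CM, CM against WT without and after irradiation, and the difference of the IR responses. P values were adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. SE of a log2 fold change comes from the quasi-likelihood fit. CPM are TMM-scaled, and log2 CPM for components and list levels used a prior count of 2.

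Before the data were examined, 32 gene lists were fixed for pathways, blood lineages and other cell types the sort could hold; 30 had at least 3 tested members. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a contrast, and again with an estimated correlation and with fry. With camera's estimated correlation the p53 target list was called after irradiation in WT and in CM, and no other list in any contrast. The response per animal is the mean over a list of log2 CPM, IR minus NIR, compared between genotypes with an exact two-sided permutation test.

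Named genes followed a rule also fixed before the data were examined. Cbfb, Myh11, Runx1, Trp53, Cdkn1a, Mdm2, Bbc3, Pmaip1 and Bax were always named. From the genes past 5%, the 6 largest log2 fold changes per direction were named if the mean was at least 5 CPM in the higher group, the groups did not overlap and the gene was not a predicted one, and up to 3 members of each fixed list with the smallest p. For the difference of responses, where 0 genes passed in edgeR, the 3 smallest p were named as not passing. Some genes that the rule would name were withheld for evaluation and are not reported.

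The tests were run on simulated counts drawn from the real means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold in each run. Each library was drawn independently, so the simulation held no animal effect. Its counts of recovered and falsely called genes do not describe libraries paired by animal. edgeR recovered 51, 36, 41, 35 and 7 of 100 changes of 2-fold and 69, 75, 73, 77 and 50 of 100 of 4-fold, for IR in WT, IR in CM, CM against WT without and after irradiation, and the difference, over 14437, 14442, 14453, 14442 and 14442 genes. It called 9, 4, 5, 3 and 2 unchanged genes, and DESeq2 called 49, 29, 42, 50 and 39. A simulated shift of 0.5 log2 units in the p53 target list was recovered by camera with 0 of 29 other lists called. Genes were drawn independently, so this cannot show how often lists are called because their genes are correlated. In the real data other groupings of the WT libraries gave up to 18 lists.

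The alternatives were DESeq2, limma-voom, RLE and upper-quartile factors, no filter or a filter of 1 CPM in 3 libraries, only the compared groups, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1) with RPKM over 1 in 3 libraries or no filter, the series term, the replicate block, the animal as a random effect, and each library left out in turn. Fits without both libraries of CM animal 2, CM animal 3 or WT animal 1 were chosen after seeing the data. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.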

Results

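RNA from lineage-negative, Sca1-positive, c-Kit-positive (LSK) bone marrow cells, the compartment that holds mouse hematopoietic stem cells and multipotent progenitors, was sequenced in 12 libraries. The cells came from wild-type (WT) mice and from preleukemic mice carrying Cbfb-MYH11 (CM), the fusion gene of inv(16) acute myeloid leukemia. Sorted cells were irradiated ex vivo with 3.5 Gy (IR) or incubated alongside without irradiation (NIR), and were harvested 24 h later. Each of the 4 groups held 3 libraries, and each of the 6 animals gave 1 NIR and 1 IR library. The labels give each animal its own number, so n counts animals within a group. Total gene counts per library ran from 68.5 to 110.8 M. The group means were 78.1 ± 10.6 M for WT NIR, 95.5 ± 14.0 for WT IR, 78.3 ± 1.48 for CM NIR and 85.3 ± 2.84 for CM IR (SD, n = 3).

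The mouse genes that the fusion is named for were looked at first. Cbfb, the subunit of core binding factor that stabilises RUNX proteins on DNA, lies on chromosome 8 (mm10, 105170674 to 105217988, plus strand). Its level was 217 ± 25 CPM in WT NIR and 248 ± 37.8 CPM in CM NIR (SD, n = 3), a log2 fold change of 0.19 ± 0.15 (SE, adjusted p = 0.573). Myh11, smooth muscle myosin heavy chain, lies on chromosome 16 (14194527 to 14291408, minus strand) and stood near the limit of counting, at 0.152 ± 0.0600 CPM in WT NIR and 0.366 ± 0.146 CPM in CM NIR. Its log2 fold change of 1.28 ± 0.44 did not pass (adjusted p = 0.195). Neither gene passed in the irradiated cells, where the log2 fold changes of CM over WT were 0.02 ± 0.15 for Cbfb and 1.22 ± 0.43 for Myh11 (adjusted p = 0.969 and 0.264). The gene counts do not separate fusion transcripts from those of the normal alleles, so they do not check the genotype labels.

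Libraries of the same group differed in how close they lay. The first principal component of log2 CPM held 51.5% of the variance and the second 21.9%. Both libraries of CM animal 1 and the NIR library of CM animal 3 stood at -78.8 to -75.0 on the first component. CM animal 2 stood at 23.0 (NIR) and 19.3 (IR) on the first component and at -67.9 and -57.2 on the second. The IR library of CM animal 3 stood at -8.92 on the first component, away from the NIR library of its own animal. The NIR library of WT animal 1 stood at -1.36, against 26.5 to 45.1 for the other WT libraries.

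**Figure D1:**
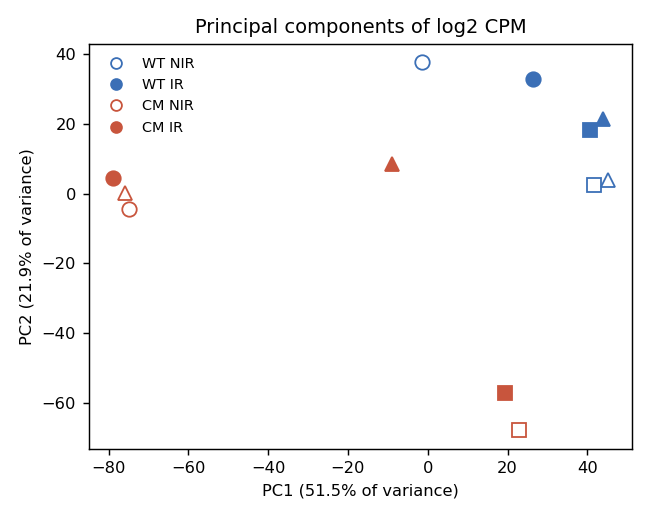
Principal components of log2 CPM over the tested genes, 1 point per library; the x axis is the first component (51.5% of variance) and the y axis the second (21.9%). Blue is WT, red is CM, open symbols are NIR, filled symbols are IR, and circles, squares and triangles are animals 1, 2 and 3 of each genotype; the 2 libraries of CM animal 3 (triangles) stand at -75.9 and -8.92 on the first component.

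The first comparison asked which transcripts differed 24 h after irradiation of WT cells. Genes induced by p53 led the change: Trp53inp1, a p53 target that promotes cell cycle arrest and death, rose from 19.7 ± 0.935 to 84.1 ± 3.86 CPM (SD, n = 3). Its log2 fold change was 2.10 ± 0.12 (SE, adjusted p = 8.75e-05; chromosome 4, 11156441 to 11174379). Ccng1, which encodes cyclin G1, rose from 164 ± 9.95 to 569 ± 42.4 CPM (1.79 ± 0.19, adjusted p = 0.0119; chromosome 11, 40748552 to 40755286). Mdm2, the ubiquitin ligase that targets p53 for degradation, rose from 90.4 ± 2.93 to 150 ± 9.95 CPM (0.73 ± 0.09, adjusted p = 0.0274; chromosome 10, 117688875 to 117710758). Zmat3, a p53-induced RNA-binding protein gene, rose from 12.3 ± 1.47 to 147 ± 10.2 CPM (3.58 ± 0.48, adjusted p = 0.0301), and Phlda3, a p53 target that restrains AKT signalling, from 1.92 ± 0.846 to 27.6 ± 3.29 CPM (3.85 ± 0.56, adjusted p = 0.041). The largest log2 fold changes among the other named genes were 4.17 ± 0.62 for the atypical cadherin gene Fat1, 3.85 ± 0.51 for Tnfsf4 (OX40 ligand), 3.68 ± 0.56 for Inka2 and 3.11 ± 0.48 for the ephrin receptor gene Epha2, with adjusted p from 0.0279 to 0.047. In all, 17 of 14599 genes were higher and 0 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 371 were higher and 220 lower, against 730 in total by chance. This fit had no animal term, so the spread between animals entered its error. A count under that of chance therefore does not measure a lack of response. DESeq2 called 120 higher and 30 lower, and limma-voom 30 higher and 1 lower. With the animal as a replicate block edgeR called 163 genes (137 higher, 26 lower), the 17 among them. Leaving out the NIR library of WT animal 1, 2 or 3 left 2, 2 and 1 genes, and leaving out the IR library of animal 1, 2 or 3 left 2, 4 and 1, with Trp53inp1 in each of the 6 fits.

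Of the list of 45 p53 target genes, 6 rose over all genes tested, 28 rose when adjusted over the list alone, and 0 fell. The fitted change was positive in 42 members, with a median log2 fold change of 0.76 (camera adjusted p = 1.57e-51; adjusted p = 0.00451 with an estimated correlation, and 0.550 with an estimated correlation and the replicate block together). Several death and arrest genes did not pass singly in the fit without an animal term. The cell cycle inhibitor gene Cdkn1a had a log2 fold change of 1.15 ± 0.27 (adjusted p = 0.221, and 0.0574 with the replicate block). Among the pro-apoptotic genes, Bbc3 (PUMA) had 1.34 ± 0.28 (adjusted p = 0.167, and 0.0443 with the replicate block). Bax had 0.99 ± 0.33 (adjusted p = 0.712, and 0.0923 with the block) and Pmaip1 (NOXA) 0.26 ± 0.12 (adjusted p = 1, and 0.250 with the block). Within WT animals 1, 2 and 3 log2 CPM rose by 0.88, 1.37 and 1.33 for Cdkn1a and by 0.74, 1.24 and 1.14 for Bax. Trp53 itself had 0.04 ± 0.19 and Runx1 0.17 ± 0.07, both with an adjusted p of 1.

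**Figure D2:**
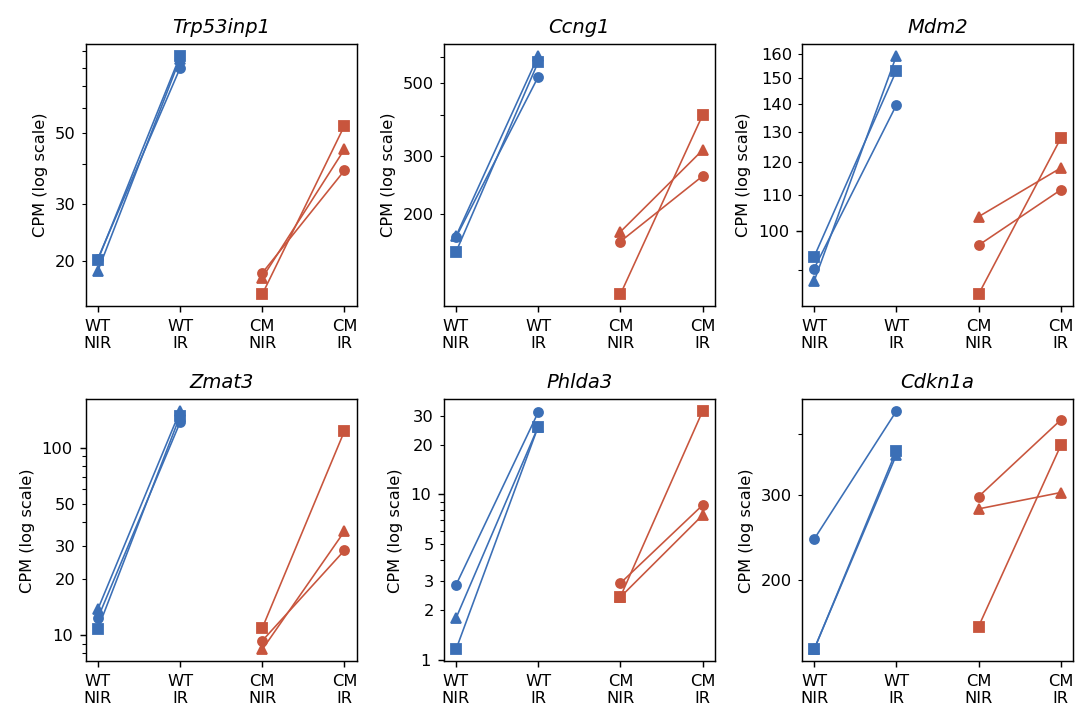
CPM on a log scale (y axis) of 6 p53 target genes in each library, by group on the x axis; lines join the NIR and IR libraries of 1 animal, blue for WT and red for CM, with circles, squares and triangles for animals 1, 2 and 3. Trp53inp1 reached 84.1 ± 3.86 CPM in irradiated WT cells and 45.2 ± 7.28 CPM in irradiated CM cells (SD, n = 3).

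Proliferation and erythroid genes stood lower after irradiation of WT cells. Of 39 mitosis genes 35 had a lower fitted level, with a median of -0.13 (camera adjusted p = 6.71e-08; adjusted p = 0.641 with an estimated correlation). Within animals the mean log2 change of the list was -0.117, -0.113 and -0.121 in WT animals 1, 2 and 3 (adjusted p = 2.79e-10 with the replicate block, 0.458 with an estimated correlation as well). The same was so of 29 of 33 homologous recombination and Fanconi anemia genes (median -0.09, adjusted p = 0.00241; 0.942 with an estimated correlation) and 36 of 43 DNA replication genes (median -0.05, adjusted p = 0.0325; 0.951 with an estimated correlation). All 15 erythroid markers had a lower fitted level (median -1.80, adjusted p = 1.17e-07; 0.641 with an estimated correlation). The erythroid list stood at 2.32 in the NIR library of WT animal 1, against -0.86 and -0.10 in those of animals 2 and 3 (mean log2 CPM relative to all libraries). Without that library the erythroid median was -0.17 (adjusted p = 0.118). Lymphoid progenitor markers were called lower (13 genes, median -0.25, adjusted p = 0.0317; 0.641 with an estimated correlation, 0.0515 with the replicate block). Myeloid progenitor markers were called higher (24 genes, median 0.23, adjusted p = 0.00241; 0.641 with an estimated correlation), as were inflammatory and NF-kB genes (25 genes, median 0.11, adjusted p = 0.0355; 0.951 with an estimated correlation). No member of these lists passed singly over all genes; adjusted over the list alone, 1 lymphoid member rose and 1 fell, and no member of the others passed.

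Single libraries decided several of these list calls in WT. Without the NIR library of WT animal 2, the calls of the recombination, lymphoid and inflammatory lists ended. Without the NIR library of WT animal 3, those of the recombination, replication, myeloid, lymphoid and inflammatory lists ended. Without the IR library of WT animal 1, those of the recombination, replication and inflammatory lists ended, and without that of animal 2 those of the replication and lymphoid lists. The highest adjusted p in these fits were 0.157 for recombination, 0.658 for replication, 0.0591 for myeloid, 0.0900 for lymphoid and 0.692 for inflammatory genes. With 1 library left out the medians ranged from -0.18 to -0.05 for recombination, -0.08 to -0.0016 for replication, 0.12 to 0.47 for myeloid, -0.50 to -0.24 for lymphoid, -2.29 to -0.17 for erythroid and -0.17 to 0.59 for inflammatory genes. The p53 target and mitosis lists were called without each library in turn, with a mitosis median as small as -0.08 without the IR library of WT animal 1. With the replicate block the mast cell and basophil markers were also called (18 genes, median 0.13, adjusted p = 0.0155, against 0.112 without it and 0.851 with the block and an estimated correlation together). The other 22 lists, mast cells included, had adjusted p from 0.112 to 0.944.

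The second comparison put the same question to CM cells. Trp53inp1 rose from 17.2 ± 1.35 to 45.2 ± 7.28 CPM (SD, n = 3), a log2 fold change of 1.39 ± 0.12 (SE, adjusted p = 0.00421). Mdm2 had a log2 fold change of 0.33 ± 0.09, Cdkn1a 0.59 ± 0.26, Bbc3 0.90 ± 0.28, Bax 0.59 ± 0.32 and Pmaip1 0.04 ± 0.12, none passing (adjusted p = 0.99996). As a group the p53 targets moved up: 42 of 45 were positive, with a median of 0.45 (camera adjusted p = 1.33e-36; adjusted p = 0.0145 with an estimated correlation, and 0.537 with an estimated correlation and the replicate block together). Of them 1 rose over all genes, 16 rose when adjusted over the list alone and 0 fell. Trp53inp1 was the 1 gene of 14599 that passed, and 0 were lower in edgeR's test. In CM 201 were higher and 36 lower at an unadjusted p under 0.05, against 730 in total by chance. As in WT, the fit had no animal term, so this count does not measure a lack of response. DESeq2 called 18 higher and 0 lower, and limma-voom 1 higher and 0 lower. With the replicate block 0 genes passed (Trp53inp1 adjusted p = 0.0997; 965 genes at an unadjusted p under 0.05). Without the NIR library of CM animal 3, or without both of its libraries, 0 genes passed, and without the IR library of CM animal 2, 3 passed.

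Mitosis genes were lower in CM cells after irradiation, 38 of 39 with a lower fitted level and a median of -0.14 (camera adjusted p = 2.38e-16; adjusted p = 0.319 with an estimated correlation). The mean change was -0.139, -0.0998 and -0.163 within CM animals 1, 2 and 3 (adjusted p = 4.15e-19 with the replicate block, 0.151 with an estimated correlation as well). Erythroid markers were called lower too, with 14 of 15 lower and a median of -0.85 (adjusted p = 1.47e-05; 0.701 with an estimated correlation). Further lists called lower were integrated stress and unfolded protein response genes (24 genes, median -0.11, adjusted p = 0.0159; 0.766 with an estimated correlation) and recombination and Fanconi anemia genes (median -0.05, adjusted p = 0.0376; 0.828 with an estimated correlation). Mature neutrophil markers were called higher (14 genes, median 0.66, adjusted p = 0.00366; 0.701 with an estimated correlation). So were B cell (9 genes, median 0.26), T and NK cell (12 genes, median 0.41) and myeloid progenitor markers (median 0.08), each at an adjusted p of 0.0472. With an estimated correlation these 3 had adjusted p of 0.342, 0.701 and 0.777, and the T and NK cell call ended with the replicate block (adjusted p = 0.0668). No member of these lists passed singly, over all genes or adjusted over the list alone. The other 21 lists had adjusted p from 0.146 to 0.974.

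The blood lineage calls in CM moved with single libraries, and some of them with the IR library of CM animal 3. In that library the mature neutrophil list stood at 0.74, against -0.77 and -0.64 in the IR libraries of CM animals 1 and 2, and the T and NK cell list at 0.26, against -0.86 and -1.05. Without it the neutrophil, B cell, T and NK cell and stress response calls ended, and the T and NK cell median turned to -0.12. Without the NIR library of CM animal 2 the recombination, myeloid, neutrophil, B cell and T and NK cell calls ended, with a myeloid median of -0.06. The IR library of CM animal 1 ended the recombination, myeloid, B cell and T and NK cell calls, and that of CM animal 2 the erythroid and stress response calls. The NIR library of CM animal 1 ended the B cell, T and NK cell and stress response calls, and that of CM animal 3 the stress response call. The highest adjusted p in these fits were 0.95 for recombination, 0.690 for myeloid, 0.419 for neutrophil, 0.327 for B cell, 0.991 for T and NK cell, 0.071 for erythroid and 0.339 for stress response genes. The medians ranged from -0.08 to 0.0010 for recombination, -0.056 to 0.20 for myeloid, 0.28 to 0.94 for neutrophil, 0.25 to 0.55 for B cell, -0.12 to 0.64 for T and NK cell, -1.56 to -0.26 for erythroid and -0.21 to -0.03 for stress response genes. The p53 target and mitosis calls stood without each library in turn, with a mitosis median as small as -0.09 without the NIR library of CM animal 3.

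The difference between the genotypes in their response to irradiation was then tested as an interaction. The p53 target list responded less in CM than in WT: the median difference of log2 fold changes was -0.37, and 41 of 45 members had a smaller fitted response in CM (camera adjusted p = 5.05e-21; adjusted p = 0.0822 with an estimated correlation). Averaged over the list, log2 CPM rose by 1.01, 1.29 and 1.30 in WT animals 1, 2 and 3 and by 0.467, 1.16 and 0.60 in CM animals 1, 2 and 3. The means were 1.20 ± 0.166 in WT and 0.743 ± 0.369 in CM (SD, n = 3), a difference of -0.45 (exact permutation test, two-sided p = 0.2, where 3 against 3 cannot go below 0.1). Without CM animal 2 the difference was -0.66 (exact p = 0.1), and without CM animal 1 it was -0.32 (exact p = 0.3). Without CM animal 3, whose irradiated library is weighed below, it was -0.38 (exact p = 0.3). Within library number series A, WT animal 1 had 1.01 and CM animals 1 and 2 had 0.467 and 1.16; within series B, WT animals 2 and 3 had 1.29 and 1.30 and CM animal 3 had 0.60.

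**Figure D3:**
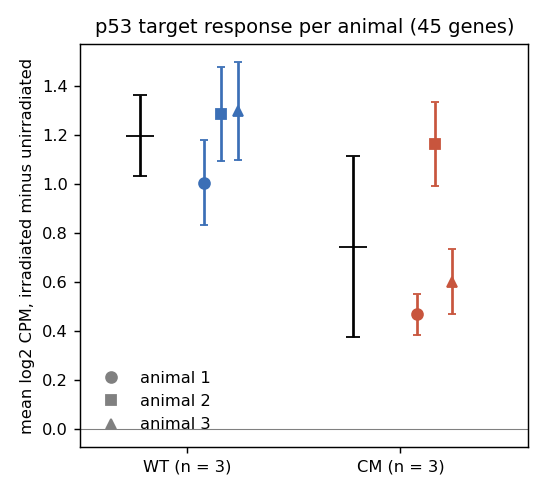
Response of 45 p53 target genes to irradiation in each animal: the y axis is the mean over the genes of log2 CPM in the IR library minus the NIR library of that animal, with bars of 1 SE over genes, and the x axis is the genotype. Black marks are the mean and SD over the 3 animals of a genotype, 1.20 ± 0.166 for WT and 0.743 ± 0.369 for CM; CM animal 2, at 1.16, lies within the WT range of 1.01 to 1.30.

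Single genes did not pass this interaction test. The smallest p values belonged to Pappa2 (log2 difference -4.64 ± 0.87, with 5 counts in all 3 WT NIR libraries together), Trp53inp1 (-0.71 ± 0.17) and Cpt1c, a carnitine palmitoyltransferase family gene (-1.88 ± 0.47), each with an adjusted p of 0.99999. Mdm2 had -0.41 ± 0.13, Cdkn1a -0.56 ± 0.37 and Bbc3 -0.44 ± 0.39. edgeR, DESeq2 and limma-voom each called 0 genes, while 106 genes had an unadjusted p under 0.05 in edgeR, against 730 by chance. The edgeR fit had no animal term, so the spread between animals entered its error. A count under that of chance therefore does not show that the responses were alike. In data simulated at this size edgeR recovered 7 of 100 changes of 2-fold and 50 of 100 of 4-fold in this interaction, over 14442 genes. The simulation held no animal effect, so these counts do not describe libraries paired by animal. Lists of blood lineages were called the other way, with a higher response in CM: lymphoid progenitor (median 0.67, adjusted p = 7.00e-04), mature neutrophil (0.52, adjusted p = 0.00608), B cell (0.64, adjusted p = 0.00608) and T and NK cell markers (0.42, adjusted p = 0.0242). With an estimated correlation these 4 had adjusted p of 0.117, 0.677, 0.113 and 0.677, and no member of the 5 called lists passed singly, over all genes or adjusted over the list alone. Without the IR library of CM animal 3 the lymphoid (median 0.02, adjusted p = 0.0670), neutrophil and T and NK cell calls ended. Without the NIR library of WT animal 1 the neutrophil, B cell (adjusted p = 0.0547) and T and NK cell calls ended, and the NIR library of CM animal 2 and the IR library of WT animal 3 each ended the neutrophil call. The lymphoid median was 1.40 without the NIR library of CM animal 2, 1.038 without the IR library of CM animal 1 and 0.43 without the NIR library of CM animal 3. The highest adjusted p for neutrophil and for T and NK cell markers were 0.529 and 0.289, with medians from 0.02 to 1.23 and from 0.17 to 0.996. With the replicate block the erythroid (median 1.13, adjusted p = 0.0158) and mast cell lists (median -0.17, adjusted p = 0.0191) were also called, each at 0.0836 without it and at 0.972 with the block and an estimated correlation together. The 25 lists not called had adjusted p from 0.0836 to 0.971.

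The third comparison asked how unirradiated CM and WT cells differed. Of the genes lower in CM, Epx, eosinophil peroxidase, stood at 60.2 ± 18.5 CPM in WT and 1.27 ± 0.704 in CM (SD, n = 3; log2 fold change -5.57 ± 0.66 SE, adjusted p = 0.00932; chromosome 11, 87863998 to 87875536). Prg2, eosinophil major basic protein, had -5.41 ± 0.72 (adjusted p = 0.0137; chromosome 2, 84980461 to 84983632), and the calprotectin genes S100a8 and S100a9 had -3.80 ± 0.74 and -3.99 ± 0.83 (adjusted p = 0.0376 and 0.0435). Of the genes higher in CM, Cd38, an NAD-consuming ectoenzyme, rose from 4.64 ± 0.776 to 37.4 ± 21.5 CPM (3.01 ± 0.52, adjusted p = 0.0245; chromosome 5, 43868809 to 43912374). Of the core binding factor genes, Runx1 rose from 212 ± 10.9 to 277 ± 6.15 CPM (0.38 ± 0.07, adjusted p = 0.0328; chromosome 16, 92601466 to 92826074). Its paralog Runx3 fell from 126 ± 5.56 to 44.0 ± 15 CPM (-1.52 ± 0.28, adjusted p = 0.0298; chromosome 4, 135120645 to 135177990). The other named increases were Bank1 (4.08 ± 0.73), a B cell scaffold gene, Synpo (3.24 ± 0.45), Tctex1d1 (3.08 ± 0.62), the homeobox gene Hopx (2.73 ± 0.54) and the adaptor gene Grap (2.64 ± 0.35), with adjusted p from 0.0130 to 0.0405. The other named decreases were Tmem119 (-6.40 ± 1.35) and the delta-catenin gene Ctnnd2 (-3.80 ± 0.69), with adjusted p of 0.0470 and 0.0299.

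Members of the fixed lists also passed singly in this comparison. Of the myeloid progenitor markers, the G-CSF receptor gene Csf3r rose from 96.9 ± 7.97 to 203 ± 50.9 CPM (log2 fold change 1.07 ± 0.21, adjusted p = 0.0376). Elane, neutrophil elastase, had -1.39 ± 0.29 (adjusted p = 0.0434). The chemokine receptor gene Cxcr2 had 2.0 ± 0.41, the P-selectin gene Selp 2.07 ± 0.41, the unfolded protein response factor gene Xbp1 0.68 ± 0.14 and the leptin receptor gene Lepr 1.68 ± 0.30 (adjusted p from 0.0290 to 0.0434). Vcam1, an adhesion receptor gene, had -2.92 ± 0.39 and the interleukin 2 receptor gene Il2rb -3.75 ± 0.77 (adjusted p = 0.0140 and 0.0434). Of the p53 pathway genes, Pmaip1 had -0.41 ± 0.12 (adjusted p = 0.131), Cdkn1a 0.48 ± 0.26 (adjusted p = 0.440), Mdm2 0.07 ± 0.09, Bax 0.35 ± 0.32, Bbc3 0.0028 ± 0.28 and Trp53 0.03 ± 0.19, none passing.

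In all, 137 genes were higher and 100 lower in unirradiated CM cells than in WT cells at an adjusted p under 0.05. DESeq2 called 524 higher and 434 lower. With library number series as a term edgeR called 180 genes. The edgeR test took the NIR and IR libraries of an animal as independent; with the animal as a random effect limma-voom called 5 genes, and all 26 gene calls that the naming rule gives for this comparison ended. These counts rested on single libraries: 914 genes passed without the NIR library of CM animal 2, 53, 20 and 15 without that of WT animal 1, 2 or 3, and 8 and 4 without that of CM animal 1 or 3. With both libraries of CM animal 2 left out 2497 genes passed, with both of CM animal 3 left out 147, and with both of WT animal 1 left out 2.

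Among blood lineage lists, mast cell and basophil markers were higher in unirradiated CM cells: 2 of 18 rose over all genes, 9 rose and 1 fell when adjusted over the list alone, and the median log2 fold change was 1.17 (camera adjusted p = 1.69e-04; adjusted p = 0.842 with an estimated correlation). The 2 were the tryptase gene Tpsb2 (3.93 ± 0.62, adjusted p = 0.0201), uncertain because counting may split its reads with its close paralog Tpsab1, and Mcpt4, with too few counts in WT for a fold. The level of this list (mean log2 CPM relative to all libraries) was 1.33 and 1.38 in CM animals 1 and 3 but -0.78 in CM animal 2, against 0.04, -1.29 and -1.26 in WT animals 1, 2 and 3. The median was 2.35 without WT animal 1. T and NK cell markers were lower in CM, with 1 of 12 fallen, 4 fallen when adjusted over the list alone, and a median of -1.37 (adjusted p = 3.93e-05; 0.382 with an estimated correlation). Mature neutrophil markers had a median of -1.10 (adjusted p = 0.0297; 0.842 with an estimated correlation). Of 14 neutrophil genes 2 rose and 2 fell over all genes, S100a8 and S100a9 down and Cxcr2 among those up, and 3 rose and 5 fell when adjusted over the list alone. The neutrophil list stood at 1.38 in the NIR library of WT animal 1, against 0.29 and 0.11 in animals 2 and 3, and its call ended without that library (median -0.36, adjusted p = 0.153) or without that of CM animal 2 (adjusted p = 0.118). Antioxidant response genes were higher, 20 of 22 positive, with a median of 0.26 (adjusted p = 2.16e-04; 0.811 with an estimated correlation); 0 rose over all genes and 2 when adjusted over the list alone. Its level was 0.23 and 0.37 in CM animals 1 and 3 and -0.12 in CM animal 2, which lay within the WT range of -0.23 to -0.07. Inflammatory and NF-kB genes had a median of 0.53 (adjusted p = 0.0288; 0.863 with an estimated correlation), with no member past 5% either way, and this call ended without the NIR library of WT animal 2 or 3 or of CM animal 1 or 3 (adjusted p up to 0.225), with medians from 0.19 to 0.85 over the 6 libraries left out in turn.

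The series title names the DNA damage response, and none of the DNA repair lists passed between unirradiated CM and WT cells. The median log2 fold change was -0.06 for recombination and Fanconi anemia genes (adjusted p = 0.293) and 0.10 for nonhomologous end joining genes (12 genes, adjusted p = 0.702). It was -0.11 for damage signalling and checkpoint genes (19 genes, adjusted p = 0.416), -0.04 for excision and mismatch repair genes (32 genes, adjusted p = 0.435), -0.05 for DNA replication genes (adjusted p = 0.197) and -0.04 for p53 target genes (adjusted p = 0.399). The end joining level, looked at after the test, was higher in each CM animal (0.07, 0.04 and 0.16) than in each WT animal (-0.06, -0.02 and -0.05). The same was so after irradiation (0.05, 0.03 and 0.10 against -0.14, -0.08 and -0.10). The excision list stood at -0.12 and -0.18 in CM animals 1 and 3 and 0.16 in CM animal 2, against -0.01, 0.0033 and 0.045 in WT. Hematopoietic stem cell markers had a median of -0.14 (38 genes, adjusted p = 0.560). The level of that list was -0.79 and -0.68 in CM animals 1 and 3 and 0.63 in CM animal 2, against -0.14, 0.37 and 0.24 in the WT animals. The 25 lists not called had adjusted p from 0.0585 to 0.949.

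**Figure D4:**
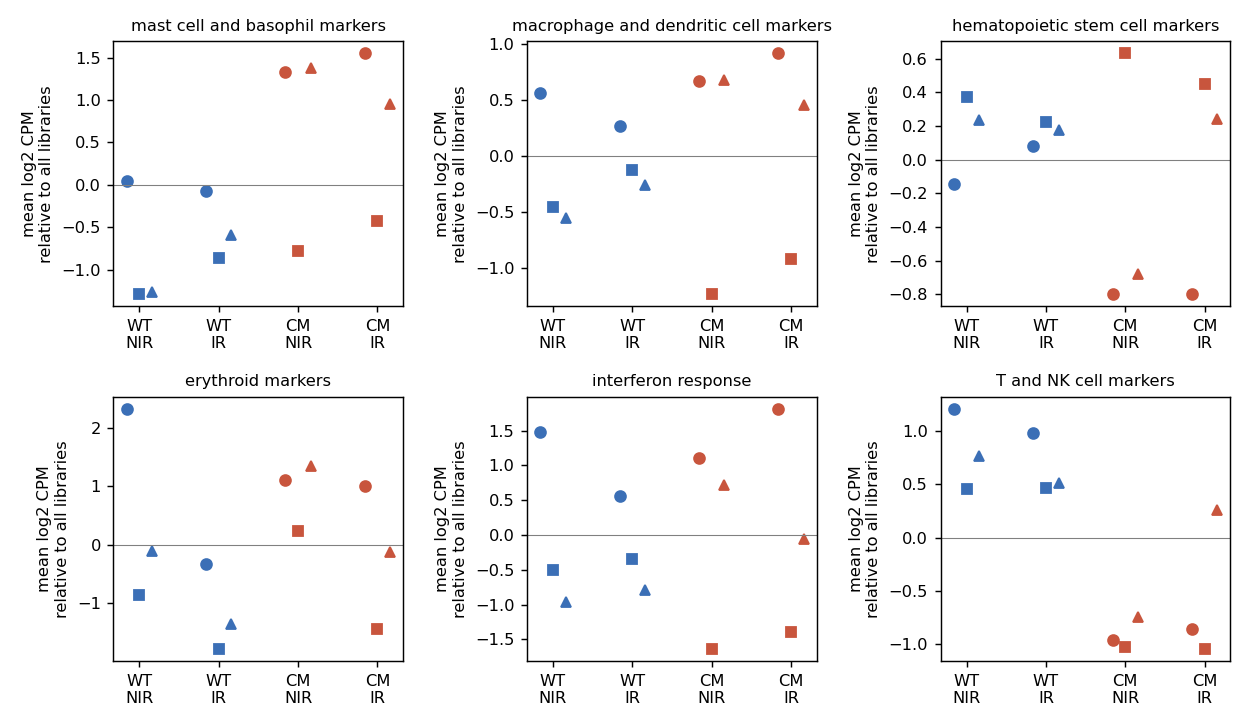
Level of 6 gene lists in each library: the y axis is the mean log2 CPM of the list relative to its mean over all 12 libraries, the x axis the group, and circles, squares and triangles are animals 1, 2 and 3 of WT (blue) or CM (red). CM animal 2 (squares) stands apart from CM animals 1 and 3 in mast cell and basophil markers without irradiation, at -0.78 against 1.33 and 1.38.

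The fourth comparison set irradiated CM cells against irradiated WT cells. p53 targets stood lower in CM: Trp53inp1 was at 45.2 ± 7.28 CPM in CM and 84.1 ± 3.86 in WT (SD, n = 3; log2 fold change -0.90 ± 0.12 SE, adjusted p = 0.0228). Pmaip1, a pro-apoptotic BH3-only gene, was at 47.1 ± 3.47 CPM in CM and 72.8 ± 4.46 in WT (-0.63 ± 0.12, adjusted p = 0.0497; chromosome 18, 66458604 to 66465558). Pmaip1 was also at a lower fitted level in CM without irradiation (-0.41 ± 0.12), and its difference of responses was -0.22 ± 0.17, neither passing. Over the list of 45, these 2 genes were lower and 0 higher, 8 were lower when adjusted over the list alone, and the median was -0.38 (camera adjusted p = 6.85e-10; adjusted p = 0.368 with an estimated correlation). Mdm2 had -0.34 ± 0.09 (adjusted p = 0.146), Bbc3 -0.44 ± 0.28, Cdkn1a -0.09 ± 0.26, Bax -0.05 ± 0.32, Trp53 0.03 ± 0.19 and Runx1 0.13 ± 0.07, none passing. The mean level of the list was 0.76 ± 0.0280 in WT and 0.21 ± 0.313 in CM, with each CM library below each WT library (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). Without irradiation the levels were -0.44 ± 0.193 and -0.53 ± 0.0646 (exact p = 0.7).

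Other genes that differed after irradiation included Syne2, which encodes nesprin-2 of the nuclear envelope, at 16.8 ± 0.695 CPM in WT and 75.8 ± 17.3 in CM (2.17 ± 0.17, adjusted p = 0.00124; chromosome 12, 75818318 to 76110928). Peg10, an imprinted retrotransposon-derived gene, stood at 3.11 ± 0.414 CPM in WT and 14.3 ± 2.27 in CM (2.20 ± 0.19, adjusted p = 0.00162; chromosome 6, 4747306 to 4760516). Bank1 (4.35 ± 0.74), Synpo (2.90 ± 0.45), Cd38 (2.71 ± 0.51) and the syndecan gene Sdc1 (2.23 ± 0.39) were also higher, with adjusted p from 0.0347 to 0.0475. Genes lower in CM were the aquaglyceroporin gene Aqp3 (-3.62 ± 0.47), Epx (-3.58 ± 0.59), Prg2 (-3.48 ± 0.65), the integrin gene Itgae (-3.05 ± 0.42), Vcam1 (-2.20 ± 0.38) and the beta-secretase gene Bace1 (-1.93 ± 0.30), with adjusted p from 0.0208 to 0.0460. Mast cell and basophil markers were again higher, with 1 of 18 risen (Mcpt4, too few counts in WT for a fold), 7 risen and 1 fallen when adjusted over the list alone, and a median of 1.30 (adjusted p = 0.0012; 0.891 with an estimated correlation). T and NK cell markers were lower in all 12 members (median -1.0, adjusted p = 4.22e-04; 0.368 with an estimated correlation) and antioxidant genes higher in 20 of 22 (median 0.19, adjusted p = 0.0012; 0.827 with an estimated correlation), with no member passing singly or when adjusted over the list alone. The mast cell level in the IR libraries of CM animals 1, 2 and 3 was 1.55, -0.42 and 0.96, against -0.07, -0.86 and -0.59 in WT. The mast cell median was 0.71 without the IR library of CM animal 1, and the T and NK cell median was -0.41 without that of WT animal 1 and -0.67 without that of CM animal 2.

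Between irradiated cells 57 genes were higher and 40 lower in CM, and DESeq2 called 437 higher and 282 lower. limma-voom called 69 higher and 87 lower, and with the animal as a random effect 7 higher and 6 lower, with 3 of the 15 calls that the naming rule gives kept. With library number series as a term 14 genes passed. Without the IR library of CM animal 3, 270 passed; without that of CM animal 1 or 2, 6 and 32; and without that of WT animal 1, 2 or 3, 3, 6 and 4. With both libraries of CM animal 3 left out 204 genes passed, with both of CM animal 2 left out 1000, with both of WT animal 1 left out 2, and with only the 2 groups fitted 0 (1608 at an unadjusted p under 0.05). The 26 lists not called had adjusted p from 0.0764 to 0.883.

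The responses of the genotypes to irradiation overlapped in 1 gene, Trp53inp1, where independent lists of 17 and 1 genes would share 0.00116; the overlap was 0 of 163 and 0 genes with the replicate block and 16 of 150 and 18 with DESeq2. All 17 genes called in WT had a positive fitted change in CM. Across genes, which are not independent replicates, the fitted changes correlated at r = 0.42. Differences between CM and WT were shared more widely: 53 genes were higher in CM both without and after irradiation, where independent lists would share 0.535, and 31 were lower in both, against 0.274. The fitted changes correlated across genes at r = 0.83, and all 237 genes called without irradiation kept their sign. Both comparisons used the same 6 animals, so part of this sharing may come from differences between animals.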

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

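All weighing tests and the fits without an animal were chosen after the results were seen; the counts over other groupings of the libraries were planned before.

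The fall in p53 target response with the CM genotype was marked because the interaction test called it with camera's preset correlation, with a median difference of -0.37; it was not called with an estimated correlation (adjusted p = 0.0822) or with fry (0.531). Higher p53 targets before irradiation are argued against: after irradiation the list stood 0.55 ± 0.18 (SE over animals) log2 units lower in CM (-0.55, CM minus WT), and without irradiation the difference was -0.09 ± 0.12. Unirradiated cells mixed into the irradiated libraries of the CM animals as a set stay open. The mitosis genes go against this, with mean changes of -0.13 ± 0.018 (SE over animals) in CM and -0.12 in WT. The WT change times 0.621, the ratio of the log2 p53 response of CM to that of WT, gives -0.073. Mixing acts on CPM and not on log2 changes, so this product does not set the change that dilution needs. The mitosis list was also not called with an estimated correlation. Other lists called in both genotypes had smaller medians in CM, as dilution would give. These were erythroid (-1.80 in WT, -0.85 in CM), myeloid progenitor (0.23, 0.08) and recombination genes (-0.09, -0.05). None of these lists was called with an estimated correlation either. Without the NIR library of WT animal 1 the WT erythroid median was -0.17, smaller than that of CM. In single animals, the erythroid change of CM animal 1 (-0.10) lay above that of each WT animal. So did the recombination and replication changes of CM animal 3 (0.05 and 0.05). The erythroid changes of CM animals 2 and 3 (-1.67 and -1.47) lay within the WT range of -2.65 to -0.92. The myeloid progenitor change of CM animal 2 (0.43) was larger than that of each WT animal. For CM animal 3 alone the mitosis change was -0.16, yet RNA of an unirradiated WT library, weighed below at shares of 0.531 and 0.486, would lower its p53 response of 0.60 and stays open. A lower response with the genotype stays open too (exact p = 0.2 between animals), as does a difference in cell makeup, which was not tested: without irradiation the mast cell list stood at 1.33 and 1.38 and the stem cell list at -0.79 and -0.68 in CM animals 1 and 3, and at -0.78 and 0.63 in CM animal 2, whose p53 response of 1.16 lay inside the WT range.

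Lists of blood lineages were marked by the same interaction test, at 0.52 for mature neutrophil, 0.67 for lymphoid progenitor, 0.64 for B cell and 0.42 for T and NK cell markers, and none of the 4 was called with an estimated correlation (adjusted p = 0.677, 0.117, 0.113 and 0.677). Without the irradiated library of CM animal 3 the neutrophil, lymphoid and T and NK cell calls ended (medians 0.43, 0.02 and 0.17), and without the NIR library of WT animal 1 the neutrophil, B cell and T and NK cell calls did (medians 0.02, 0.76 and 0.20). The NIR library of CM animal 2 and the irradiated library of WT animal 3 each ended the neutrophil call (medians 0.77 and 0.29).

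On the first component the irradiated library of CM animal 3 lay between the WT libraries and the NIR library of its own animal. In log2 CPM it correlated more with each WT library (r from 0.983 to 0.985) than with any other CM library. Those correlations ran from 0.974 to 0.981, the highest with the NIR library of its own animal. A library of a WT animal under a CM label was weighed over the genes called higher in unirradiated CM cells. The share of irradiated WT RNA that, added to the NIR library of the animal, would give its levels had a median of 0.557. The quartiles were 0.444 to 0.630, where a library like the mean of the irradiated WT libraries needs about 1. Those genes were picked with the NIR libraries of CM animal 3 and of WT. A WT animal unlike these therefore stays open as the source of this library. RNA of a WT library mixed in may account for its place and stays open, because with the NIR library of WT animal 3 as donor the shares from genes higher and lower in CM were 0.531 and 0.486, a gap of 0.0458 ± 0.0355 (SE; the other 5 donors gave gaps of 0.0792 to 0.195). With the mean of the irradiated WT libraries as donor the shares were 0.557 and 0.380, and single genes chosen after their values were seen gave 0.151 for Epx, 0.167 for Prg2 and 1.09 for Hlf. A different makeup of the sorted cells of that animal was not tested.

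Mast cell and macrophage genes were higher in CM animals 1 and 3 than in CM animal 2. The macrophage list stood at 0.67 and 0.68 in the first 2 and -1.24 in the last without irradiation, and at 0.56 in WT animal 1 against -0.46 and -0.55 in the other WT animals, so high macrophage genes were not particular to CM. For the gap between CM animals 1 and 2 the library number series is argued against, since both are of the same series. The mast cell list stood 2.12 ± 0.20 (SE over genes, not over animals) log2 units higher in the former without irradiation and 1.97 ± 0.23 after it. In WT without irradiation its level was 0.04 in animal 1 (series A) and -1.29 and -1.26 in animals 2 and 3 (series B). Mature mast cells among the sorted cells may contribute and stay open: the granule protease genes Mcpt4, Cma1, Tpsb2 and Tpsab1 together stood at 16.8 CPM in the unirradiated library of CM animal 1 and 11.7 in that of CM animal 3, against a WT mean of 1.47. No profile of mature mast cells was used here to set the level they would need. The lineage and Sca1 gates of the sort are meant to exclude mature cells, but whether they exclude mast cells was not checked.

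Runx1 and Pappa2 moved in opposite directions in all 3 animals of each genotype after irradiation, and this difference between animals was not tested (edgeR's interaction test, given with the results, called 0 genes): the mean log2 response differed by -0.26 for Runx1 (0.06 to 0.25 in WT, -0.13 to -0.07 in CM) and by -3.32 for Pappa2, which had very few counts. Of 50 named genes looked at, a share of 0.03125 would do so if the sign in each animal were random and independent. This share does not describe genes picked from these data, as most of the named genes were. Pappa2 is among them, named for its small p in the interaction test. The B cell list did so too, with a mean difference of 0.85 (untested in this form).

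Other groupings of the same libraries were too few to give a share under 0.05, since 3 against 3 make 10; the counts below include the real grouping. After irradiation in WT, 1 of the 10 gave as many genes as the real 17 (highest other 0) and 6 as many lists as 8 (highest other 18). In CM, 2 gave as many genes as the real 1 and 6 as many lists as 9 (highest other 16); the highest other, 4123 genes, set both libraries of CM animal 1 and the NIR library of CM animal 3 against the rest, which points to a structure of the samples. Among the 4 groupings that part all 3 animal pairs, the highest other was 0 genes in WT and in CM, and 18 and 16 lists. Without irradiation, 2 gave as many genes between CM and WT as the real 237; the highest other, 928, set WT animal 1 with CM animals 1 and 3 against the rest, again a structure of the samples, and all 10 gave as many lists as 5 (highest other 17). After irradiation 1 gave as many genes as the real 97 (highest other 0) and 9 as many lists as 4 (highest other 16). For the difference of responses all 10 groupings of the animals gave 0 genes and 6 gave as many lists as 5 (highest other 16).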

How the results depend on the processing

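Fits without both libraries of an animal were chosen after seeing the data; the other alternatives were planned. No named gene that passed in edgeR changed direction in an alternative where it was fitted. A named call ended in 58 gene fits for IR in WT, 5 for IR in CM, 250 for CM against WT without irradiation and 130 after it. It was counted as kept in the others, 16, 310 and 195 in the last 3 comparisons. A gene to which a fit gave no adjusted p was also counted as kept. The cause of each move below was not tested unless fewer libraries or genes were fitted. In the order IR in WT, IR in CM, CM against WT without and after irradiation, edgeR called 17, 1, 237 and 97 genes and DESeq2 150, 18, 958 and 719. limma-voom gave 31 in WT and 156 between irradiated cells (69 higher and 87 lower, against 57 and 40 in edgeR), and the animal as a random effect 5 and 13 between genotypes, with 0 of 26 and 3 of 15 named calls kept. Only the compared groups gave 92, 0, 78 (25 higher and 53 lower, against 137 and 100) and 0, with a spread taken from 6 libraries. The strict filter gave 57 and the series term 14 between irradiated cells. log2(RPKM + 1) gave 147 (67 higher, 80 lower) without irradiation, log2(RPKM + 0.1) 144 (70 higher, 74 lower) and 40 between irradiated cells (16 higher, 24 lower), and log2(RPKM + 1) with no filter 53 in WT, 179 between irradiated cells (47 higher, 132 lower) and 2 for the difference of responses. The replicate block gave 163 in WT and 0 in CM, and beyond the calls given with the results it changed no other list or named gene call of a paired comparison. CM and WT replicate numbers do not pair (different animals; correlations 0.53, 0.38 and -0.37 without and 0.39, 0.13 and 0.14 after irradiation), and with the number as a block 854 and 416 genes were called. The overlap of IR responses was 1 gene, 0 with the block and 16 with DESeq2.

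With an estimated correlation the lists called were 1, 1, 0, 0 and 0 (the last for the difference of responses) and with fry 1, 1, 1, 0 and 0, against 8, 9, 5, 4 and 5; the p53 medians of -0.38 between irradiated cells (adjusted p = 0.368 and 0.0715 with fry) and -0.37 for the difference (0.0822 and 0.531) were not called. With 1 library left out, genes ranged from 1 to 4 in WT, 0 to 3 in CM, 4 to 914 and 3 to 270 between genotypes and 0 for the difference; lists from 5 to 13, 5 to 15, 4 to 15, 4 to 8 and 3 to 16. The p53 median ranged from 0.75 to 0.82 in WT, 0.32 to 0.60 in CM, -0.53 to -0.32 between irradiated cells and -0.46 to -0.26 for the difference, and the difference of the response per animal from -0.66 to -0.32. In CM after irradiation the myeloid progenitor median ranged from -0.056 to 0.20 and that of T and NK cells from -0.12 to 0.64. Without CM animal 3, 0, 147 and 204 genes passed (IR in CM, then between genotypes). Without CM animal 2, 3, 2497 and 1000 did, with 12 and 9 lists between genotypes and 9 for the difference. Without WT animal 1, 1 gene passed for IR in WT and 2 and 2 between genotypes, with 15 and 8 lists. Without CM animal 3 and with the block, 0 genes and 17 lists were called for IR in CM, a T and NK cell median of -0.030, and 3 lists for the difference. Depth limits the precision of genes under 1 CPM, such as Myh11 and Pappa2 in WT.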

Other observations

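Values in this part were chosen after the data were seen. Interferon response genes (37 tested) differed between animals of the same group. Their level without irradiation was 1.48, -0.50 and -0.97 in WT animals 1, 2 and 3 and 1.11, -1.64 and 0.72 in CM animals 1, 2 and 3 (mean log2 CPM relative to all libraries), and the list was not called in any contrast. After irradiation it changed by -0.91, 0.15 and 0.17 in the WT animals and by 0.70, 0.25 and -0.78 in the CM animals. Erythroid markers had mean log2 changes of -2.65, -0.92 and -1.25 in the WT animals and -0.10, -1.67 and -1.47 in the CM animals. The small change of CM animal 1 had an SE over genes of 0.057, and no animal was tested singly.

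Progenitor and mast cell genes showed the spread between CM animals gene by gene, in genes chosen after their values were seen. Fcer1a, a chain of the IgE receptor, stood at 281, 24.7 and 450 CPM in the unirradiated libraries of CM animals 1, 2 and 3, and at 4.41 to 15.5 CPM in those of WT. The carboxypeptidase gene Cpa3 stood at 405, 66.4 and 538 CPM and the interleukin 33 receptor gene Il1rl1 at 370, 42.6 and 467 CPM. The transcription factor gene Hlf went the other way, at 20, 127 and 18.8 CPM. In the irradiated library of CM animal 3 it stood at 60.7 CPM, against 64.2 CPM in that of WT animal 2.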
